A study of Petunia x hybrida with 6 samples.

How the data were processed

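Polyadenylated RNA was sequenced from the corolla (the petals of the flower) of Petunia x hybrida cultivar Mitchell, per the labels. The plants grew in a greenhouse with 14 h of light, from 6 AM to 8 PM, and 10 h of dark. There were 3 libraries from 7AM and 3 from 7PM. The labels number the replicates but do not say whether they came from separate plants, so p-values measure the spread between these samples, which may in part be technical.

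The authors deposited 1 table of whole-number read counts per gene, not normalized, with 35812 gene IDs and a column for each of the 6 libraries. Reads were aligned to a Petunia axillaris reference genome, per the design text of the series. The submitters' processing notes name cutadapt, TopHat2 and HTSeq. Their versions and settings, the genome release, the annotation and the handling of strand and of reads with several matches are not given in the sources used here. Petunia x hybrida is a hybrid, so counts against a P. axillaris reference may be lowered for genes inherited from the other parent, and reads of near-identical gene copies may be lost or split. Columns were tied to samples by the sample descriptions. The table held no row without a gene ID and no duplicated ID. In 2884 IDs a letter t stands where the others have g. Of these, 2849 had 0 counts in all libraries, and the table does not say what the letter marks.

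The table does not pair its IDs with gene names, functions or coordinates, and no annotation was used here. The 18 gene lists written before the data were examined (floral volatile synthesis, clock genes, photosynthesis, markers of other flower parts and others) were therefore not applied, and results are given by ID, abundance and size of change. By the rule fixed beforehand for this case, 4 IDs are named, the 2 that rose and the 2 that fell the most among genes with an adjusted p under 0.05, a mean of at least 10 CPM over all libraries and no overlap between the groups.

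Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr by time (17638 genes), libraries were scaled with TMM, and a quasi-likelihood test (glmQLFit and glmQLFTest) compared 7PM with 7AM, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Fold changes are 7PM over 7AM, so a positive log2 value is higher at 7PM. CPM values are counts divided by the TMM-scaled library size, per 1000000. The SE of a log2 fold change comes from the spread of log2 CPM (prior count of 2) between the libraries. It is not the SE of the edgeR estimate beside it, and the prior count narrows it where libraries hold few counts. Single values per library were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Between-library scaling matters in these data because TMM factors were 1.15 ± 0.01 (SD, n = 3) at 7AM and 0.87 ± 0.02 (SD, n = 3) at 7PM. Scaling to library totals alone moves the fold change of every gene by 0.39 on the log2 scale towards lower values at 7PM.

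Library totals ran from 16497054 to 18040038 counts, and the 17638 tested genes held at least 99.9% of each total. No pair of libraries was identical. Counts of replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom from 6.98 (7AM replicates 1 and 2) to 31.8 (7PM replicates 1 and 2). Intervals and limits from counts cover counting error only.

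The edgeR step was tested on simulated data with 17392 genes passing the filter, drawn from the means, library sizes and dispersions of the 6 libraries. It recovered 90.9% of genes changed 4-fold, 62.1% of those changed 2-fold and 22.4% of those changed 1.5-fold, with 8.7% false calls among all calls. DESeq2 1.42.0 recovered 92.4%, 77.3% and 47.8%, with 28% false calls. limma-voom (limma 3.58.1) recovered 84.8%, 60.6% and 17.9%, with 7.7% false calls. Only 66 or 67 of the genes passing the filter were changed at each size, up or down. The dispersion of a gene was the same at both times, and composition did not shift. In the real libraries 59.9% of tested genes were called and TMM factors differed between the times, so these rates need not carry over. The alternatives were DESeq2 size factors, library totals and upper-quartile factors for scaling, no filter and a minimum of 1 CPM on average, DESeq2 and limma-voom as tests, the replicate number as a block, the 10 most abundant genes left out, and each library left out in turn. A test against a 2-fold change (glmTreat) and thinning of counts to equal effective library size were added after seeing the data.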

Results

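Transcripts of the petunia corolla were counted at 7AM and at 7PM. Mitchell is a white-flowered cultivar whose petals release benzenoid and phenylpropanoid scent compounds mainly at night. The 7AM samples were taken 1 h after the lights came on at 6 AM, and the 7PM samples 1 h before they went off at 8 PM. Each time had 3 libraries. Total counts were 17277765, 16990908 and 16497054 for 7AM replicates 1 to 3 and 18040038, 17410929 and 17431191 for 7PM replicates 1 to 3. Of 35812 gene IDs, 11577 (32.3%) had 0 counts in all 6 libraries, and 17638 had enough counts to be tested. Libraries separated by time on the first principal component of log2 CPM, which held 86.5% of the variance. Pearson's r between libraries, across genes, was 0.987 to 0.991 within 7AM, 0.971 to 0.98 within 7PM and 0.818 to 0.846 between the times.

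The comparison of 7PM with 7AM asks which transcript levels differ between the evening and the morning of the light period. Most tested genes differed. At an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 4852 genes were higher and 5714 were lower at 7PM, together 59.9% of those tested. Changes of at least 2-fold were called for 2304 higher and 2812 lower genes, 29% of those tested. Changes of at least 8-fold were called for 500 higher and 528 lower genes, and of at least 32-fold for 135 higher and 96 lower genes. The CPM of the groups did not overlap in 67.6% of tested genes, where chance gives 10% for 3 libraries against 3. Without 7AM replicate 2, which lay further from the 7PM libraries than the other 7AM replicates, 4169 genes were higher and 4857 lower. The counts were 4238 and 4984 without 7AM replicate 1, and 4328 and 5041 without 7AM replicate 3. Leaving out any 7AM library thus lowered them. Without 7PM replicate 1 there were 5365 higher and 5358 lower genes. The counts were 4882 and 5205 without 7PM replicate 2, and 4712 and 5024 without 7PM replicate 3.

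The split between higher and lower genes depended on scaling. With TMM, 45.9% of the called genes were higher at 7PM. Scaled to library totals alone, 2835 genes (23.1% of called genes) were higher and 9443 were lower. The 8-fold class then held 393 higher and 711 lower genes. Of the 5116 genes called at least 2-fold under TMM, 4970 were also called in the same direction under library totals. The shift of 0.39 on the log2 scale is too small to turn the sign of a 2-fold change.

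**Figure D1:**
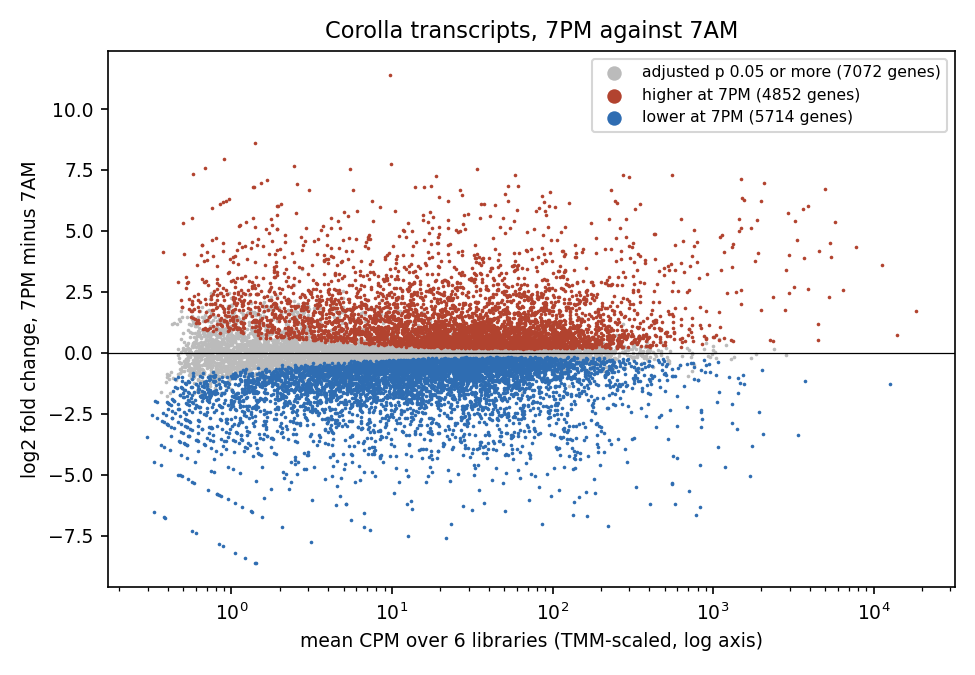
Each point is 1 of the 17638 tested genes, with its mean CPM over the 6 libraries (TMM-scaled, log axis) on the x axis and its log2 fold change, 7PM minus 7AM, on the y axis. The 4852 genes called higher and the 5714 called lower lie on both sides of 0, and the most abundant genes lie mostly above it. The fitted fold changes of genes with 0 counts at 1 time depend on the prior count.

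The gene with ID Peaxi162Scf00154g01024 rose the most under the rule for named genes. Its level was 0.363 ± 0.095 CPM at 7AM and 67.7 ± 10.1 CPM at 7PM (SD, n = 3), a log2 fold change of 7.52 ± 0.22 (SE) with an edgeR adjusted p of 1.86e-06. Its counts were 5, 8 and 8 at 7AM and 915, 1142 and 1053 at 7PM. Peaxi162Scf00439g00037 rose from 0.723 ± 0.344 to 115.2 ± 17.6 CPM (SD, n = 3), a log2 fold change of 7.30 ± 0.40 (SE) with an edgeR adjusted p of 2.54e-06. These genes were 184-fold and 158-fold higher at 7PM. Their IDs place them on scaffolds 154 and 439 of the reference, and the deposited table gives no coordinates or function for either.

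Peaxi162Scf00763g00412 fell the most, from 43.4 ± 12.0 CPM at 7AM to 0.221 ± 0.219 CPM at 7PM (SD, n = 3). Its log2 fold change was -7.60 ± 0.56 (SE), with an edgeR adjusted p of 1.08e-05. The gene had 864, 1063 and 596 counts in the 7AM libraries and 2, 7 and 1 in the 7PM libraries. Without 7PM replicate 2, which held the 7 counts, the fitted log2 fold change was -8.69. The other 2 libraries then hold 3 counts, for which the log2 ratio to 7AM was -8.82 (95% exact Poisson interval -11.1 to -7.27, counting error only). Peaxi162Scf00058g00138 fell from 25.1 ± 16.3 to 0.131 ± 0.067 CPM (SD, n = 3), a log2 fold change of -7.52 ± 0.81 (SE) with an edgeR adjusted p of 0.000516. Its 7AM counts were uneven, with 610 and 721 in replicates 1 and 3 and 130 in replicate 2, and limma-voom gave an adjusted p of 0.0672. Their IDs place these genes on scaffolds 763 and 58.

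The most abundant genes, those with a mean of at least 1000 CPM, changed by at least 2-fold more often than the other classes, and mostly upwards. Of the 94 genes with a mean of at least 1000 CPM, 50 were at least 2-fold higher and 19 at least 2-fold lower at 7PM. In the class of 100 to 1000 CPM, 363 genes were at least 2-fold higher and 247 lower among 1819. Between 10 and 100 CPM the 2-fold numbers were 1029 higher and 1114 lower among 8992 genes. Among 5665 genes of 1 to 10 CPM they were 735 higher and 1156 lower, and among 1068 genes under 1 CPM they were 127 higher and 276 lower. The odds of a 2-fold call being upwards were 3.26 times as high in the class of at least 1000 CPM as in the other genes together (95% confidence interval 1.88 to 5.87, Fisher's exact test, two-sided, p = 4.21e-06). That test runs across genes, which are not independent replicates. Scaled to library totals, 48 genes of this class were at least 2-fold higher and 22 lower. Genes called at any size of change made up 88.3% of the class of at least 1000 CPM, 74.5% of that of 100 to 1000 CPM and 40% of the genes under 1 CPM. Small changes are called more easily in genes with more counts, so these shares do not compare how often genes changed.

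**Figure D2:**
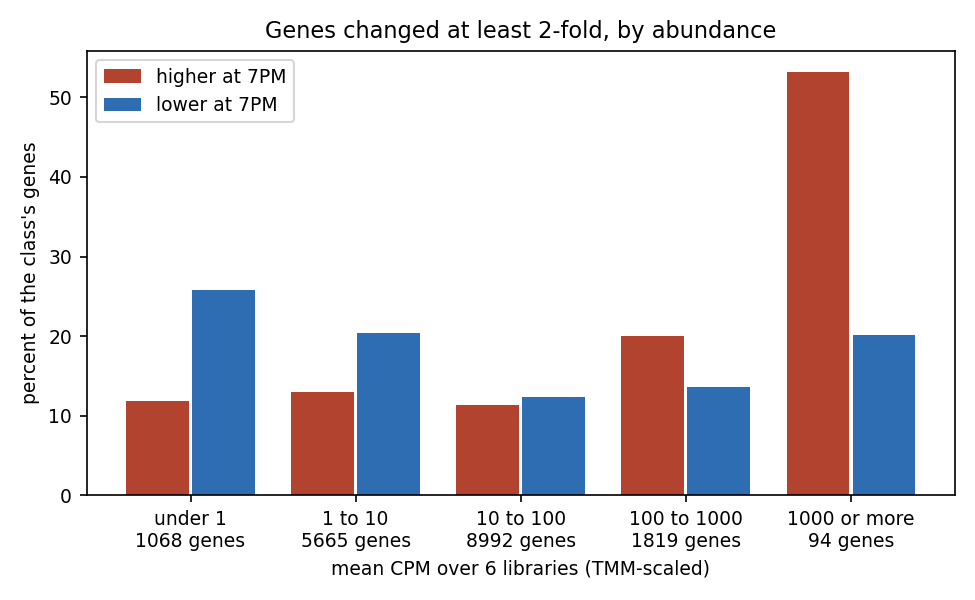
Bars show the percent of tested genes called at least 2-fold higher or at least 2-fold lower at 7PM, in 5 classes of mean CPM over the 6 libraries (TMM-scaled) on the x axis. In the class of at least 1000 CPM, 53.2% of genes were higher and 20.2% lower, while under 1 CPM 11.9% were higher and 25.8% lower.

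The genes that rose came to hold a large part of the counted transcripts. The 500 genes at least 8-fold higher at 7PM held 1.47 ± 0.30% of all counts at 7AM and 22.7 ± 0.19% at 7PM (SD, n = 3). The 1804 genes that were 2- to 8-fold higher went from 8.22 ± 0.38% to 21.5 ± 0.60%. In the other direction, the 528 genes at least 8-fold lower held 8.20 ± 0.45% at 7AM and 0.41 ± 0.09% at 7PM, and the 2284 genes that were 2- to 8-fold lower went from 17.9 ± 0.51% to 4.56 ± 0.25%. The 7072 genes that were not called held 27.0 ± 0.26% at 7AM and 20.5 ± 0.92% at 7PM. The classes were made from the same libraries, so these shares describe the change and do not test it.

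**Figure D3:**
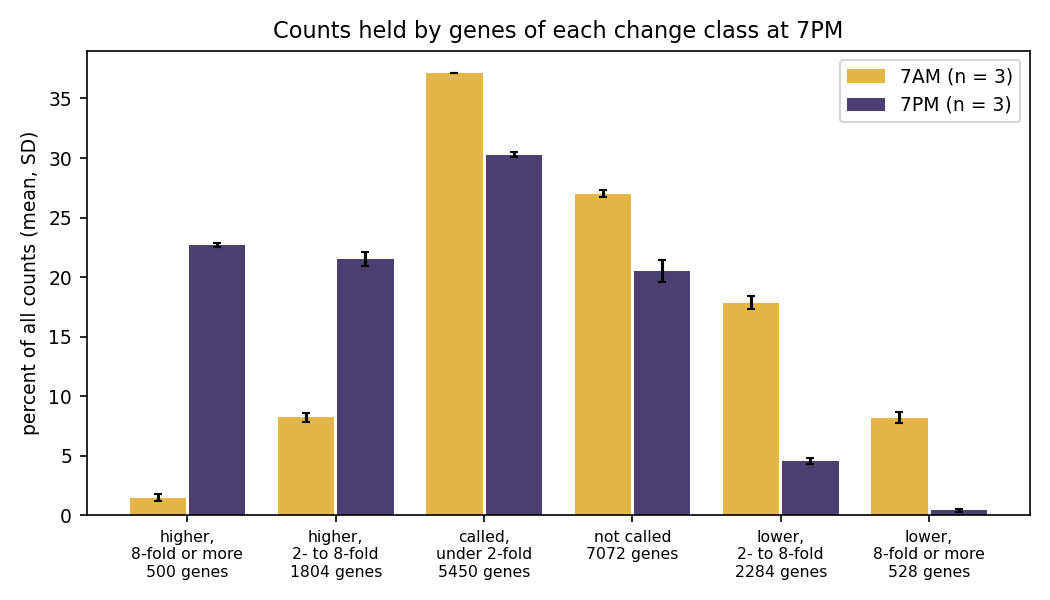
Bars show the mean percent of all counts (y axis; error bars are the SD, n = 3 libraries) held at 7AM and at 7PM by genes of 6 classes of change, from at least 8-fold higher to at least 8-fold lower at 7PM. The 500 genes at least 8-fold higher held 1.47% at 7AM and 22.7% at 7PM.

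The most abundant genes were largely different at the 2 times. Of the 100 most abundant genes at 7AM and the 100 at 7PM, 35 were shared, where independent lists would share 0.57. Independent lists are a weak yardstick, since log2 CPM of libraries from the 2 times correlated at 0.818 to 0.846. Among the 100 at 7PM, 73 were at least 2-fold higher than at 7AM, 49 of them at least 8-fold. Among the 100 at 7AM, 45 were at least 2-fold lower at 7PM and 11 were at least 2-fold higher. Each list was picked for high levels at its own time, which favours such differences. These numbers therefore describe the lists and do not test the change.

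Counts were concentrated in fewer genes at 7PM. The 10 most abundant genes of each library held 7.53 ± 0.25% of counts at 7AM and 12.4 ± 0.10% at 7PM (SD, n = 3). The difference of 4.91 percentage points separated the groups completely, at the smallest p that 3 libraries against 3 allow (exact permutation test, two-sided, p = 0.1). The 50 most abundant genes held 15.8 ± 0.57% and 27.5 ± 0.59% (SD, n = 3). In spite of the larger totals at 7PM, fewer genes reached 10 counts there. The number was 17463 ± 83.5 at 7AM and 17084 ± 172 at 7PM (SD, n = 3), also without overlap (exact permutation test, two-sided, p = 0.1). Effective library size is the total times the TMM factor. With counts thinned to equal effective library size the difference ended, at 9.33 more genes at 7PM (exact permutation test, two-sided, p = 0.9). The number of genes with at least 1 count was 21613 ± 114 at 7AM and 21426 ± 231 at 7PM (SD, n = 3), and the ranges overlapped (exact permutation test, two-sided, p = 0.4). Of the tested genes, 16 had 0 counts in all 3 libraries of 1 time, 5 of them at 7AM and 11 at 7PM. Their mean at the other time was at most 19.3 CPM for the 5 and 2.84 CPM for the 11. All 16 were called, but such genes pass the filter only through the time where they have counts. Their calls are therefore no separate result.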

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

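The glmTreat test and the thinning to equal effective size were chosen after seeing the data. Scaling was the choice that changed the counts of genes most. With library totals alone, 2835 genes were higher and 9443 lower, and the 2-fold counts were 1591 higher and 4371 lower. This follows from the shift of 0.39 on the log2 scale, and 760 of the 10566 genes called under TMM then changed sign. With upper-quartile factors the counts were 4618 higher and 5950 lower, and with DESeq2 size factors 5348 and 5208. DESeq2 as a test gave 5226 higher and 4917 lower genes, so which direction held more genes was not settled by these data. Tested with glmTreat, 1589 genes were higher and 1821 lower, and 1176 and 2885 with library totals. Leaving out each library in turn gave 4169 to 5365 higher and 4857 to 5358 lower genes, with the lowest counts without 7AM replicate 2. Both highest counts came without 7PM replicate 1, where higher and lower genes were about even. The counts of genes stayed within 1.5 times under all other settings. Of the 60 log2 fold changes of the 4 named genes under the alternatives, 59 kept their direction and stayed under the threshold. The exception was Peaxi162Scf00058g00138 under limma-voom, with -7.02 and an adjusted p of 0.0672, where the other alternatives gave adjusted p from 1.57e-19 (DESeq2) to 0.00343. The lower number of genes with 10 counts at 7PM, -379, ended at equal effective library size (9.33). It was -465.7 when thinned to the smallest total, -605 at a minimum of 1 CPM and -280.7 to -441.7 with 1 library left out. No pairing of the samples by replicate number was seen, though 3 libraries at each time are too few to exclude one. Deviations of same-numbered libraries correlated at -0.24, 0.10 and 0.08, and those of other pairs reached 0.26 (libraries did not all go best with their own number). With the replicate number as a block, 4544 genes were higher and 5367 lower. The other 9 splits of the 6 libraries into 3 and 3 gave 0 genes each in edgeR (at most 345 at an unadjusted p under 0.05, and 87 in DESeq2), where the real split gave 4852 and 5714 and, at 2-fold, 2304 and 2812. All 9 mixed the times in each group, which widens its spread, so they cannot measure false calls. Only the real split was as large, and 10 are too few for a share under 0.05. Gene lists could not be tested without gene names.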

Other observations

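Of the tests in this part, the median difference in falling genes, the constant share in 7AM replicate 3, the thinning to equal effective size, the comparison of adjacent genes with genes 2 places apart and the correlations at 3, 4 and 5 places apart were chosen after the data or the results were seen. The 7PM libraries differed more from each other than the 7AM libraries. The biological coefficient of variation (the spread between replicates beyond counting error) was 20.9% over the 3 libraries of 7PM and 9.9% over those of 7AM.

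Scaled to library totals, the median log2 fold change of all tested genes was -0.451, and fewer genes were detected at 7PM. Leaving out the 50 most abundant genes, of which 31 were at least 2-fold higher at 7PM, moved the median to -0.218 (-0.257 to -0.191 with 1 library left out), and leaving out 1000 genes moved it to -0.13. The larger share of these 50 genes at 7PM therefore covers part of the shift but not all of it. The lower detection remained when counts were thinned to the smallest total (-465.7 genes) and ended at equal effective library size (9.33 genes). Effective size includes the TMM factor, which brings most genes to a similar level at both times. This end therefore cannot tell fewer reads left for the other genes at 7PM from a fall of most transcripts. A fall of most transcripts per cell cannot be told apart from a change in shares, because counts are relative and no spike-in was used here.

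Among the 7AM libraries, replicate 2 lay further from the 7PM libraries than replicates 1 and 3. Across 10905 genes of at least 10 CPM, which are not independent, replicate 3 minus replicate 2 correlated at 0.409 with 7PM minus replicate 1. After thinning to equal effective size the correlation was 0.396. These genes hold many counts and the 7AM totals were close, so thinning could hardly lower it and cannot decide on depth. The other 2 such correlations within 7AM, with no library on both sides, were -0.301 (replicate 2 minus 1) and 0.208 (replicate 3 minus 1), and the 3 within 7PM lay between -0.029 and 0.046. Mixed-in 7PM material in replicates 1 and 3 was weighed with replicate 2 left out of the calls and a mean of at least 10 CPM. The 300 genes at least 8-fold higher at 7PM would need a share of 1.15%. That share predicts a difference of only 0.017 on the log2 scale in the 254 genes at least 8-fold lower. There replicate 2 was higher by 0.154 (95% bootstrap interval 0.136 to 0.175). The interval resamples genes, which are not independent, and leaves out the spread between libraries. Mixing at that share alone falls short of this difference, which rests on 1 library against 2. For the rising genes mixing stays open, since 0% of the 300 had an upper 95% Poisson limit of the 7AM to 7PM ratio below 0.5 times that share (1 of 335 genes with no minimum CPM and at least 5 counts expected from mixing). A constant share in 7AM replicate 3 alone was tested apart. The median share needed was 2.02% in genes with a higher 7AM level relative to 7PM and 1.13% in the others. Their ratio was 1.78 (95% bootstrap interval 1.08 to 2.19). A constant share would give equal values, but the interval spanned the limit set for this test, so the test cannot decide. The share and the grouping of genes are both relative to 7PM, which can by itself move the ratio. This interval also resamples genes and leaves out the spread between libraries. A difference in harvest time or flowers may also be the source but was not tested.

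Genes next to each other changed together slightly more than chance. With genes ordered by the scaffold and number in their IDs, which is assumed to follow their order on the scaffold, the log2 fold changes of 9932 adjacent pairs correlated at 0.104 (Spearman's rho 0.091), above all of 10000 shuffled orders, whose highest was 0.038 (p = 1e-04, the smallest these can give). The test was planned only for an order given with the data or a reference, and here it is assumed. In the deposited order the number steps down at 896 places within scaffolds. Of 3676 adjacent pairs with both genes called, 56% changed in the same direction, where 50.3% is expected from the calls alone. The correlation was 0.035 at 2 places apart, 0.029 at 3, 0.03 at 4 and 0.005 at 5 (5 distances computed, Benjamini-Hochberg adjusted p = 0.0027, 0.009, 0.009 and 0.667, and 5e-04 for adjacent genes). A transcript split over adjacent gene models may account for the excess of adjacent genes over those 2 places apart (0.035), which stays open without coordinates. For genes 3 places apart it is not excluded, because their 0.029 passed the limit set for the shuffled orders, 0.021, by 0.008, which is less than the SD of those orders, 0.011. Tandem copies of a gene that share reads or regulation remain untested.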
